A study of Mus musculus with 12 samples.

How the data were processed

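RNA was sequenced from cultures of CD4 T cells of C57BL/6 mice. Naive cells had been activated with antibodies to CD3 and CD28, cultured for 4 days either with TGF-β and IL-6 (the TGF-β condition) or with IL-6, IL-1β and IL-23 (the IL-23 condition), and restimulated for 4 hours on plate-bound anti-CD3. The 3 genotypes were wild type (WT), Src2 KO and Src2/3 DKO. The last is called labelled DKO here, because its Ncoa2 level was near that of WT. With 2 libraries per genotype and condition there were 12 libraries in 6 groups, and groups were taken from the sample labels.

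The submitters' notes name Trim Galore 0.4.4 for trimming, HISAT2 for alignment to mm10, featureCounts of the Subread package for counting and DESeq2 for analysis. The files that the authors deposited hold FPKM, fragments scaled by exon length and library size, for 18152 genes in each library. The unit was checked on the values: whole read numbers could be recovered from the steps between values for 18152 genes, within a tolerance of 0.01 read, up to a factor shared by all libraries for 3 genes. The exon lengths this implies equal those of GENCODE M21 for 17421 of 17700 genes (98.42%). The library size in the unit follows median-of-ratios size factors, within 1.32%, rather than the total of each library. The lowest total of a gene over the 12 libraries was 20 reads, so a gene missing from the files may have had reads. Recovered reads came to 14880920 to 16586604 per library. Floors of 3 reads cover counting error only.

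The analysis fixed before the data were examined assumed counts. As the values are FPKM, the test was limma 3.58.1 in R 4.3.3 on log2 of FPKM plus a pseudocount of 0.5, with 6 group means, 6 residual degrees of freedom and moderated variances with an intensity trend. The pseudocount and the filter were set after the unit was known. Genes needed an FPKM of at least 1 in 2 or more libraries, which left 12285 genes tested and 5867 not tested. The pseudocount understates fold changes of genes with low values, and it can make a gene near 0 in 1 condition appear to differ between conditions. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each of 9 comparisons; a gene passed at an adjusted p under 0.05. The comparisons were Src2 KO minus WT, labelled DKO minus WT and labelled DKO minus Src2 KO in each condition, IL-23 minus TGF-β condition in WT, and the difference between conditions of the Src2 KO and labelled DKO effects. In simulated data for the comparison of labelled DKO with WT in the TGF-β condition, 65 of 100 genes seeded with a log2 fold change of 1 were called (median estimate 0.93). So were 93 of 100 seeded with 2 (median 1.84), and 13 of 12085 unchanged genes, or 7.6% of the calls.

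There were 27 gene lists with 423 genes, written before the data were examined. They cover the SRC family, core, pathogenic and non-pathogenic Th17 genes, regulatory T cells, Th1, Th2 and follicular helper cells and the early T cell receptor response. Others hold cholesterol, fatty acid, glycolysis and respiratory chain genes, the cell cycle, interferon, coregulators, homing, naive and memory cells, apoptosis, stress, the mitochondrial genome, and T cell identity. The rest mark CD8 T and natural killer cells, γδ T cells, B cells, myeloid cells and erythroid cells. The 24 lists with at least 3 genes tested were compared with all other genes by camera of limma with a preset correlation of 0.01. No list passed with a correlation estimated from the data, in any of the 9 comparisons, so each list call rests on the preset value; its adjusted p under both is given. In simulated data a seeded list was called (adjusted p = 7.787e-34) and 0 of 20 random lists were, by camera. Simulated genes were drawn independently, so this does not show how often lists of correlated genes would be called at the preset value. Fold-change correlations were computed across genes and compared with 100 simulated sets of unchanged groups.

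Genes are named by a rule fixed before the data were examined: Ncoa1, Ncoa2 and Ncoa3; the 4 members of each described list with the smallest p; Il17a, Il17f, Il22, Csf2, Ifng, Il23r, Foxp3, Tbx21 and Il10 in every comparison. To these come the 8 higher and 8 lower genes with the largest fold change among those past the test with a mean log2 value of at least 2 and non-overlapping libraries, without unnamed gene models. The text prints part of the genes that the rule gives, and some of its results are not reported. Mki67, Rrm2, members of lists named for going against their list, B cell and myeloid markers, and genes that set a knockout line apart (a gap of at least 1 on the log2 scale) were chosen after the values were seen.

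Alternatives were voom on recovered reads, other scalings, other filters, stricter thresholds, a fit of the libraries of a comparison alone, a replicate block, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. Scaling by TMM and by total reads and pseudocounts of 0.1 and 1 were added after the data were seen. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads by exon were not analysed here.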

Results

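RNA sequencing measured the transcripts of mouse CD4 T cells that had been cultured for 4 days into Th17 cells, the helper T cells that make IL-17, and restimulated for 4 hours with plate-bound anti-CD3. The cells came from C57BL/6 mice and were labelled wild type (WT), Src2 KO or Src2/3 DKO, the last called labelled DKO. SRC2 and SRC3 are steroid receptor coactivators, proteins that help nuclear receptors and other transcription factors to activate genes, and the Ncoa2 and Ncoa3 genes encode them. Cultures held either TGF-β and IL-6 (called the TGF-β condition) or IL-6, IL-1β and IL-23 (called the IL-23 condition), so the 12 libraries formed 6 groups of 2. The labels do not say whether the 2 replicates of a group came from separate animals or cultures, so every p-value rests on the spread between these samples, which may be technical only. The variance of each gene was taken from all 6 groups together, not from the compared libraries alone. Replicate spread was unequal: chi-square per gene, against sampling noise, was 27.2 in Src2 KO and 4.47 in WT of the TGF-β condition. Tests with that Src2 KO group may therefore understate its spread, and other tests may overstate theirs. The authors deposited FPKM values, and whole reads were recovered from them. In the TGF-β condition these were 15447161 and 16586604 reads for WT, 14880920 and 15486039 for Src2 KO and 15653696 and 15879842 for the labelled DKO. In the IL-23 condition they were 16133779 and 15160435 for WT, 15080063 and 14923933 for Src2 KO and 14980869 and 15361273 for the labelled DKO. A gene without any read could have had up to 3 reads by counting error alone, which is 0.181 to 0.202 RPM (reads scaled to the library total) in these libraries. Means are given with the SD of 2 libraries throughout, in FPKM.

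The libraries separated first by cytokine condition, along a principal component that held 51.9% of the variance, and then by the labelled DKO genotype, along a second that held 16.5%. On the third component, with 8.9% of the variance, Src2 KO replicate 1 of the TGF-β condition stood at 26.65 and the other 11 libraries between -13.91 and 16.48. The cell cycle genes of that library were lower than in Src2 KO replicate 2: all 27 genes of the cell cycle list lay below, with a median log2 difference of -1.19. Mki67, a marker of dividing cells, was at 3.85 FPKM in replicate 1 and 14.2 FPKM in replicate 2. Transcripts of the mitochondrial genome took 3.41% of the reads in labelled DKO replicate 2 of the IL-23 condition and 1.95% to 2.60% in the other libraries.

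**Figure D1:**
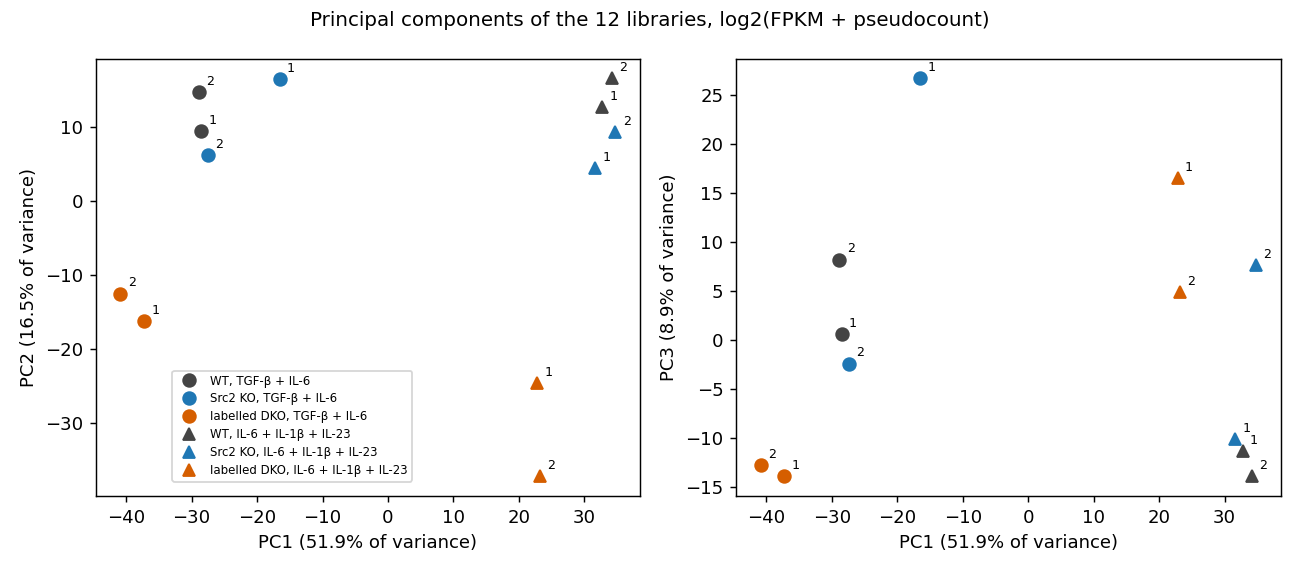
Principal components of the 12 libraries, from log2 FPKM with a pseudocount; axes give component scores and their share of the variance, colours the genotype, symbols the cytokine condition and digits the replicate. The first component separates the cytokine conditions, the second the labelled DKO libraries, and Src2 KO replicate 1 of the TGF-β condition stands at 26.65 on the third.

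The targeted genes were examined first. Ncoa2 (ENSMUSG00000005886.14, chromosome 1, 13139105 to 13374083, mm10) was at 10.5 ± 0.69 FPKM in WT, 5.56 ± 0.15 in Src2 KO and 9.47 ± 0.51 in labelled DKO cells of the TGF-β condition, or 52.9% and 90.1% of WT. In the IL-23 condition it was at 10.4 ± 0.55, 4.61 ± 0.13 and 8.77 ± 0.13 FPKM, or 44.5% and 84.7% of WT. Src2 KO cells thus had less Ncoa2 than WT in the TGF-β condition (log2 fold change -0.86, adjusted p = 0.0102) and in the IL-23 condition (-1.09, adjusted p = 0.00137). Labelled DKO cells did not pass the test in either (-0.14, adjusted p = 0.357, and -0.23, adjusted p = 0.103). Ncoa2 was higher in labelled DKO than in Src2 KO cells by a log2 fold change of 0.72 in the TGF-β condition (adjusted p = 0.00185) and 0.86 in the IL-23 condition (adjusted p = 0.000364). Ncoa3 (ENSMUSG00000027678.17, chromosome 2, 165992636 to 166073242) fell in labelled DKO cells to 26.7% of WT in the TGF-β condition (log2 fold change -1.87, adjusted p = 8e-05) and 29.0% in the IL-23 condition (-1.73, adjusted p = 1.11e-05). In Src2 KO cells Ncoa3 was at 90.6% and 97.9% of WT. Ncoa1, which encodes the related coactivator SRC1, fell in labelled DKO cells of the IL-23 condition (-0.60, adjusted p = 0.00329) and did not pass the test in the TGF-β condition (-0.16, adjusted p = 0.370). Gene totals do not show which exons the reads cover, so they cannot tell a transcript with deleted exons from a whole one. The drop of Ncoa2 in the TGF-β condition lost its call without WT replicate 1, without WT replicate 2 and without Src2 KO replicate 1, with log2 fold changes from -0.92 to -0.80 over the libraries left out in turn.

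**Figure D2:**
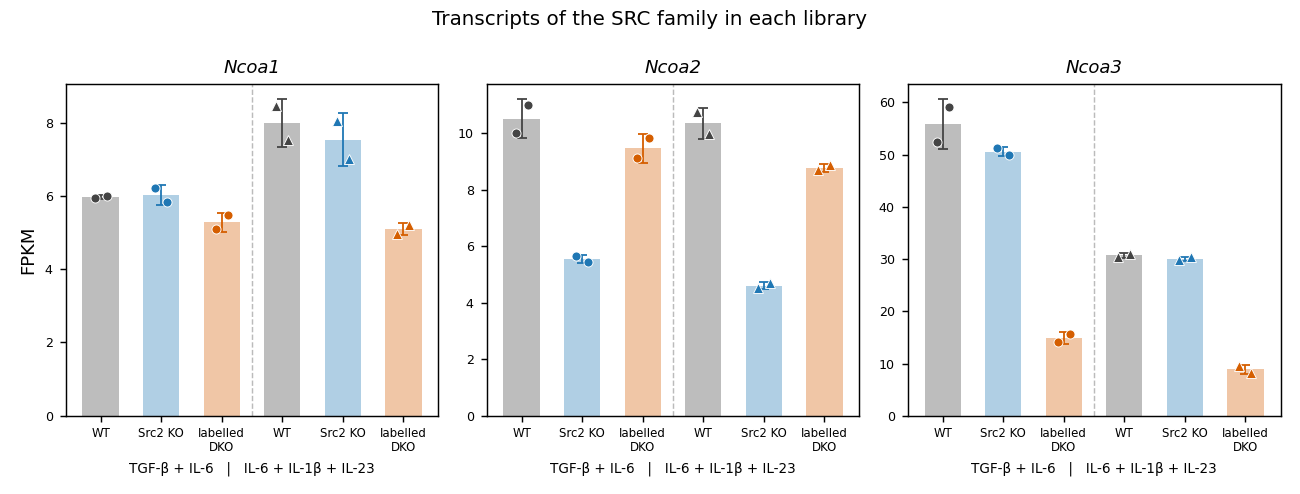
FPKM of Ncoa1, Ncoa2 and Ncoa3 in each library; bars are group means, error bars the SD of 2 libraries and points the libraries. Ncoa2 is lowest in Src2 KO cells (5.56 and 4.61 FPKM) and at 9.47 and 8.77 FPKM in labelled DKO cells, where Ncoa3 is at 14.9 and 8.91 FPKM.

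The WT cells of both conditions were compared to describe the background on which the knockouts act. Il22, a Th17 cytokine, rose from 0.138 ± 0.20 FPKM in the TGF-β condition to 26.4 ± 11 FPKM in the IL-23 condition (log2 fold change 5.37, SE 0.40, adjusted p = 2.71e-05). Il17a rose from 1063 ± 18 to 2189 ± 420 FPKM (1.03, adjusted p = 0.01), and Il17f (0.51), Il23r (0.75), Csf2 (0.82) and Tbx21 (1.10) rose too. Among the genes with the largest increase were Lum (6.41), Il24 (6.34), Tpbg (5.31), Il1r2, which encodes a decoy receptor for IL-1 (4.77), Enpp2 (4.49) and Gzmb, a cytotoxic protease (4.29). Ccl20, a chemokine for cells with the receptor CCR6, fell from 234 ± 15 to 1.79 ± 0.74 FPKM (-6.72, adjusted p = 7.22e-07). Aqp3 (-3.32), Klf2 (-3.09), Nt5e (-2.75), Foxp3, the regulator of regulatory T cells (-1.51), and Ncoa3 (-0.85) fell as well. Ifng (0.46, adjusted p = 0.167) and Il10 (0.44, adjusted p = 0.541) did not pass the test.

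Of the fixed gene lists, the Th1 list was higher in the IL-23 condition (6 of 12 genes rose, adjusted p = 0.00205; adjusted p = 0.196 with an estimated correlation). So were the stress list (9 of 16 rose, adjusted p = 0.00121; 0.244 with an estimated correlation) and the glycolysis list (7 of 20 rose, adjusted p = 0.0172; 0.579 with an estimated correlation). The cell cycle list was higher too (4 of 27 rose, adjusted p = 0.00121; adjusted p = 0.595 with an estimated correlation), with Ccne2 at a log2 fold change of 1.78. Of the markers of CD8 T and natural killer cells, 5 of 6 rose and 1 fell (adjusted p = 0.0209; adjusted p = 0.196 with an estimated correlation). The myeloid genes tested rose, Cd68 by 1.92 (adjusted p = 0.00236) and Cst3 by 0.34 (adjusted p = 0.0146), the latter a call that ended without WT replicate 1 of the TGF-β condition or WT replicate 2 of the IL-23 condition. Of 5 genes of the B cell list 2 rose, H2-Eb1 (1.34, adjusted p = 0.00175) and Cd74 (1.22, adjusted p = 0.0041), and the list did not pass (adjusted p = 0.149). The list of non-pathogenic Th17 genes was lower (5 of 7 fell and 1 rose, adjusted p = 0.0248), as was that of coregulators (7 of 16 fell, adjusted p = 0.0114), each with an adjusted p = 0.196 with an estimated correlation. Lists of fatty acid (up), interferon (up), T cell identity (down) and regulatory T cell genes (down) passed at adjusted p = 0.0365 to 0.0417, with an adjusted p = 0.455 to 0.579 with an estimated correlation. In all, 3540 of 12285 genes tested passed, 1668 higher and 1872 lower in the IL-23 condition. The count was 2008 and 1993 without WT replicate 1 and 2 of the TGF-β condition, and 2229 and 2201 without those of the IL-23 condition. The calls of Il17a, Il17f and Csf2 ended without either WT library of the TGF-β condition or without WT replicate 2 of the IL-23 condition, and that of Il23r without WT replicate 1 of the first or replicate 2 of the second. The fatty acid and T cell identity lists lost their call without either Src2 KO library of the TGF-β condition and without WT replicate 2 and 1 of the IL-23 condition. The interferon list lost it without either Src2 KO library or WT replicate 1 of the TGF-β condition, and the regulatory T cell list without WT replicate 2 of the TGF-β condition.

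The first knockout question was what the Src2 KO changes in the TGF-β condition. The IL-17 cytokines were lower in Src2 KO than in WT cells: Il17a fell from 1063 ± 18 to 297 ± 84 FPKM (log2 fold change -1.87, SE 0.23, adjusted p = 0.0268). Il17f fell from 1259 ± 94 to 507 ± 22 FPKM (-1.31, SE 0.14, adjusted p = 0.0141). Ccl20 fell from 234 ± 15 to 48.7 ± 8.7 FPKM (-2.26, adjusted p = 0.0223) and the chemokine gene Ccl3 from 121 ± 4.4 to 57.1 ± 10 FPKM (-1.09, adjusted p = 0.0421). Serinc3 rose by 0.57 (adjusted p = 0.0195). The other genes followed in every comparison and reported here did not pass: Tbx21, the Th1 regulator T-bet, came closest (-1.02, adjusted p = 0.0571). Il23r was at -0.34, Csf2 at 0.38, Foxp3 at 0.28, Il22 at -0.23, Il10 at -0.23 and Ifng at 0.00. The core Th17 list was lower (adjusted p = 1.25e-06; adjusted p = 0.249 with an estimated correlation): 3 of its 16 genes fell, and 8 fell and 1 rose adjusted over the list alone. None of the 25 early T cell receptor response genes passed over all genes, and 9 fell adjusted over the list alone; that list was lower as a whole (adjusted p = 2.48e-08; adjusted p = 0.249 with an estimated correlation). The glycolysis list was higher (adjusted p = 0.000147; adjusted p = 0.424 with an estimated correlation), with 0 of 20 genes past the test over all genes and 2 adjusted over the list alone. That call ended without Src2 KO replicate 1, the library that stands apart, at adjusted p = 0.387. A further 6 lists passed, all lower, at adjusted p = 0.0204 to 0.0482 (adjusted p = 0.249 to 0.562 with an estimated correlation): SRC family, pathogenic Th17, cholesterol, homing, naive and memory, and T cell identity. The SRC family list among them holds 3 genes with the targeted Ncoa2, so its call includes the knockout itself. Its other genes, Ncoa1 (0.01) and Ncoa3 (-0.14), did not pass. Each of these 6 lost its call without WT replicate 2 and without Src2 KO replicate 2, and the cholesterol and homing lists also without Src2 KO replicate 1; the homing list lost it too without any WT or labelled DKO library of the IL-23 condition.

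In limma's test 13 of 12285 genes passed, 2 higher and 11 lower, with 1031 at an unadjusted p under 0.05. The count of 13 was 1 without WT replicate 1, without WT replicate 2 or without Src2 KO replicate 1, and 75 without Src2 KO replicate 2. It was 6 without either labelled DKO library of the TGF-β condition, 7 without either of the IL-23 condition, 51 with voom on recovered reads and 1 in a fit of the 4 libraries of the comparison alone. The calls of Il17a, Il17f, Ccl20, Ccl3 and Serinc3 ended without WT replicate 1, WT replicate 2 or Src2 KO replicate 1 and in the fit of those 4 libraries. The calls of Ccl20 and Serinc3 also ended without either labelled DKO library of the TGF-β condition, that of Il17a without either of the IL-23 condition, and Ccl3 kept its call without 3 of the 12 libraries. Their log2 fold changes kept their sign: those of Il17a ranged from -2.16 to -1.58 and those of Il17f from -1.39 to -1.23. With a pseudocount of 0.1 the call of Ccl20 ended.

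The same question was asked in the IL-23 condition. Il17f fell from 1794 ± 219 to 833 ± 101 FPKM in Src2 KO cells (log2 fold change -1.11, SE 0.14, adjusted p = 0.0141). Maf, a transcription factor of Th17 and other helper T cells, fell from 30.2 ± 1.3 to 14.7 ± 0.62 FPKM (-1.02, adjusted p = 0.0287). Cd24a, which encodes a surface glycoprotein, fell by 1.13 on the log2 scale (adjusted p = 0.0141). Gata3, the main transcription factor of Th2 cells, rose from 5.75 ± 0.13 to 11.8 ± 0.51 FPKM (0.97, SE 0.11, adjusted p = 0.00868). Prex1 (1.59), Nppc, the gene of C-type natriuretic peptide (1.28), Zbp1, a sensor of nucleic acids induced by interferon (0.85), and Serinc3 (0.54) rose as well. Il17a was at 2189 ± 420 FPKM in WT and 1024 ± 117 in Src2 KO cells and did not pass (-1.09, adjusted p = 0.182). Il22 (-1.06), Tbx21 (-0.76), Il23r (-0.66), Ifng (-0.19), Il10 (-0.16), Foxp3 (0.11) and Csf2 (0.46) did not pass either, at adjusted p = 0.159 or above. The core Th17 list was lower (adjusted p = 5.92e-09; adjusted p = 0.126 with an estimated correlation): 1 of its 16 genes fell over all genes and 10 fell adjusted over the list alone. The Th2 list was higher (adjusted p = 9.1e-06; adjusted p = 0.116 with an estimated correlation), with 1 of 7 genes risen over all genes and 4 adjusted over the list alone. The cholesterol list was lower (adjusted p = 8.21e-10; adjusted p = 0.182 with an estimated correlation) although none of its 24 genes passed by either adjustment. The lists of non-pathogenic Th17, Th1, fatty acid and SRC family genes, the last with the targeted Ncoa2, were also lower. They stood at adjusted p = 0.00715 to 0.033 (adjusted p = 0.182 to 0.334 with an estimated correlation). These calls ended without WT replicate 1 for the SRC family list and without WT replicate 2 or Src2 KO replicate 2 for the fatty acid list. The non-pathogenic Th17 and Th1 lists lost theirs without WT replicate 1, Src2 KO replicate 1 or either labelled DKO library of the IL-23 condition, and the Th1 list also without WT replicate 2.

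In this comparison 30 genes passed, 9 higher and 21 lower, with 802 at an unadjusted p under 0.05. The count was 9 and 4 without WT replicate 1 and 2, 12 and 8 without Src2 KO replicate 1 and 2, 61 with voom on recovered reads, 49 with genes above 1 RPM and 2 in a fit of the 4 libraries of the comparison alone. Ncoa2 and Prex1 kept their calls without each library in turn. Those of Il17f, Gata3, Serinc3 and Maf ended without any 1 of the 4 libraries compared, and that of Maf also without either WT library of the TGF-β condition or either labelled DKO library of the IL-23 condition. The call of Cd24a ended without either WT library or Src2 KO replicate 2, that of Nppc without WT replicate 2 or either Src2 KO library and that of Zbp1 without WT replicate 2.

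Libraries labelled Src2/3 DKO were compared with WT in the TGF-β condition to see what changes where Ncoa3 is lowered; their Ncoa2 level was near that of WT, as given above. Il23r, the receptor of IL-23, fell from 18.3 ± 1.5 to 2.93 ± 0.46 FPKM (log2 fold change -2.46, SE 0.18, adjusted p = 0.000263). Il1r1, a receptor of IL-1, fell by 2.15 on the log2 scale, Tbx21 by 2.11, Maf by 1.45 and Il7r, the receptor of IL-7, by 1.41. Il17f fell from 1259 ± 94 to 496 ± 66 FPKM (-1.35, adjusted p = 0.00108). Il17a fell from 1063 ± 18 to 416 ± 108 FPKM (-1.38, adjusted p = 0.0102). Csf2 (-0.11), Foxp3 (0.10), Ifng (0.13), Il22 (-0.24) and Il10 (-1.14) did not pass, at adjusted p = 0.219 or above. The core Th17 list was lower (9 of 16 genes fell and 2 rose, adjusted p = 0.000195; adjusted p = 0.225 with an estimated correlation). The genes that rose were Ccr6, a chemokine receptor of Th17 cells (1.22, adjusted p = 0.0192), and Stat3 (0.39, adjusted p = 0.022); these calls were not examined without single libraries. Among the genes past the test that the rule for named genes allows, the largest fall was that of Hic1, a transcriptional repressor (-3.59). Scd1, a fatty acid desaturase (-2.55), Ltb4r1, a receptor of leukotriene B4 (-2.54), Stra6 (-2.40) and Ccl3 (-1.89) also fell, and Nppc (2.28) and Alcam (1.51) rose.

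Genes of cholesterol synthesis fell together in this comparison: 17 of 24 fell and none rose (adjusted p = 6.44e-20; adjusted p = 0.136 with an estimated correlation). Among them were Fdft1 (-1.15), Mvd (-0.93) and Sqle (-0.86). Of 19 interferon-stimulated genes 4 rose (adjusted p = 0.000403; adjusted p = 0.301 with an estimated correlation), with Isg20 at 1.17. The pathogenic Th17 list was lower (5 of 16 fell and 2 rose, adjusted p = 0.011; adjusted p = 0.301 with an estimated correlation), as was the non-pathogenic one (3 of 7 fell, adjusted p = 0.00187; adjusted p = 0.136 with an estimated correlation). Markers of CD8 T and natural killer cells were higher (1 of 6 rose, adjusted p = 0.0271; adjusted p = 0.225 with an estimated correlation). Of 5 genes of the B cell list 2 rose, Cd74 (0.96, adjusted p = 0.0422) and Ighm (0.70, adjusted p = 0.0249), and the list did not pass (adjusted p = 0.168). Both calls ended without any 1 of the 4 libraries compared, and that of Cd74 also without any Src2 KO or labelled DKO library of the IL-23 condition. The mitochondrial genome list was lower (adjusted p = 0.00932; adjusted p = 0.313 with an estimated correlation) with none of its 15 genes past the test. The SRC family (1 of 3 fell, the targeted Ncoa3), glycolysis (1 of 20 fell), respiratory chain (0 of 32) and fatty acid lists (2 of 17 fell, 1 rose) were lower. The early T cell receptor list was higher (3 of 25 rose, 1 fell). All of these lists passed at adjusted p = 0.00348 to 0.0293 (adjusted p = 0.225 to 0.464 with an estimated correlation). The calls of the respiratory chain, fatty acid and CD8 and natural killer lists ended without WT replicate 1, those of the fatty acid and early T cell receptor lists without labelled DKO replicate 2. In all 740 genes passed, 349 higher and 391 lower in labelled DKO cells. The count was 272 and 152 without WT replicate 1 and 2, 231 and 193 without labelled DKO replicate 1 and 2, 1179 and 1171 without Src2 KO replicate 1 and 2 of the TGF-β condition, and 1514 in a fit of the 4 libraries alone. The call of Il17a ended without either WT library or labelled DKO replicate 1, and that of Isg20 without WT replicate 2.

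In the IL-23 condition the labelled DKO cells had far fewer IL-17 transcripts than WT cells and more of the Th2 cytokines. Il17a fell from 2189 ± 420 to 192 ± 12 FPKM (log2 fold change -3.49, SE 0.23, adjusted p = 3.67e-05). Il17f fell from 1794 ± 219 to 159 ± 9.2 FPKM (-3.48, SE 0.14, adjusted p = 2.57e-06) and Il22 from 26.4 ± 11 to 2.19 ± 1.5 FPKM (-3.38, adjusted p = 0.000656). Maf fell from 30.2 ± 1.3 to 1.93 ± 0.032 FPKM (-3.66) and Cd24a from 84.9 ± 2.2 to 6.39 ± 0.12 FPKM (-3.63). Il23r (-2.60), Il1r1 (-2.60) and Tbx21 (-2.04) fell, while Il10 did not pass (0.03, adjusted p = 0.978). Gata3 rose from 5.75 ± 0.13 to 24.4 ± 1.9 FPKM (1.99, SE 0.11, adjusted p = 1.11e-05). Il4 rose from 2.88 ± 0.73 to 31.8 ± 2.9 FPKM (3.27, adjusted p = 4.97e-05) and Il13 from 11.2 ± 1.2 to 104 ± 34 FPKM (3.12, adjusted p = 0.000108). The chemokine gene Ccl3 rose from 71.9 ± 13 to 649 ± 54 FPKM (3.17, adjusted p = 4.57e-06). Fasl, the ligand of the death receptor Fas (3.72), Il3 (2.98), Gzmb (2.69), Ccl4 (2.57), Cd40lg (2.04) and Csf2, the gene of GM-CSF (1.70), rose as well. Foxp3 rose from 0.369 ± 0.20 to 1.62 ± 0.067 FPKM (1.31) and Ifng from 0.249 ± 0.053 to 1.25 ± 0.34 FPKM (1.21). Nppc (4.19) and Nrp1, a receptor of semaphorins (2.70), rose, and Ifitm1 (-3.20) and Pdpn, podoplanin (-3.12), fell.

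**Figure D3:**
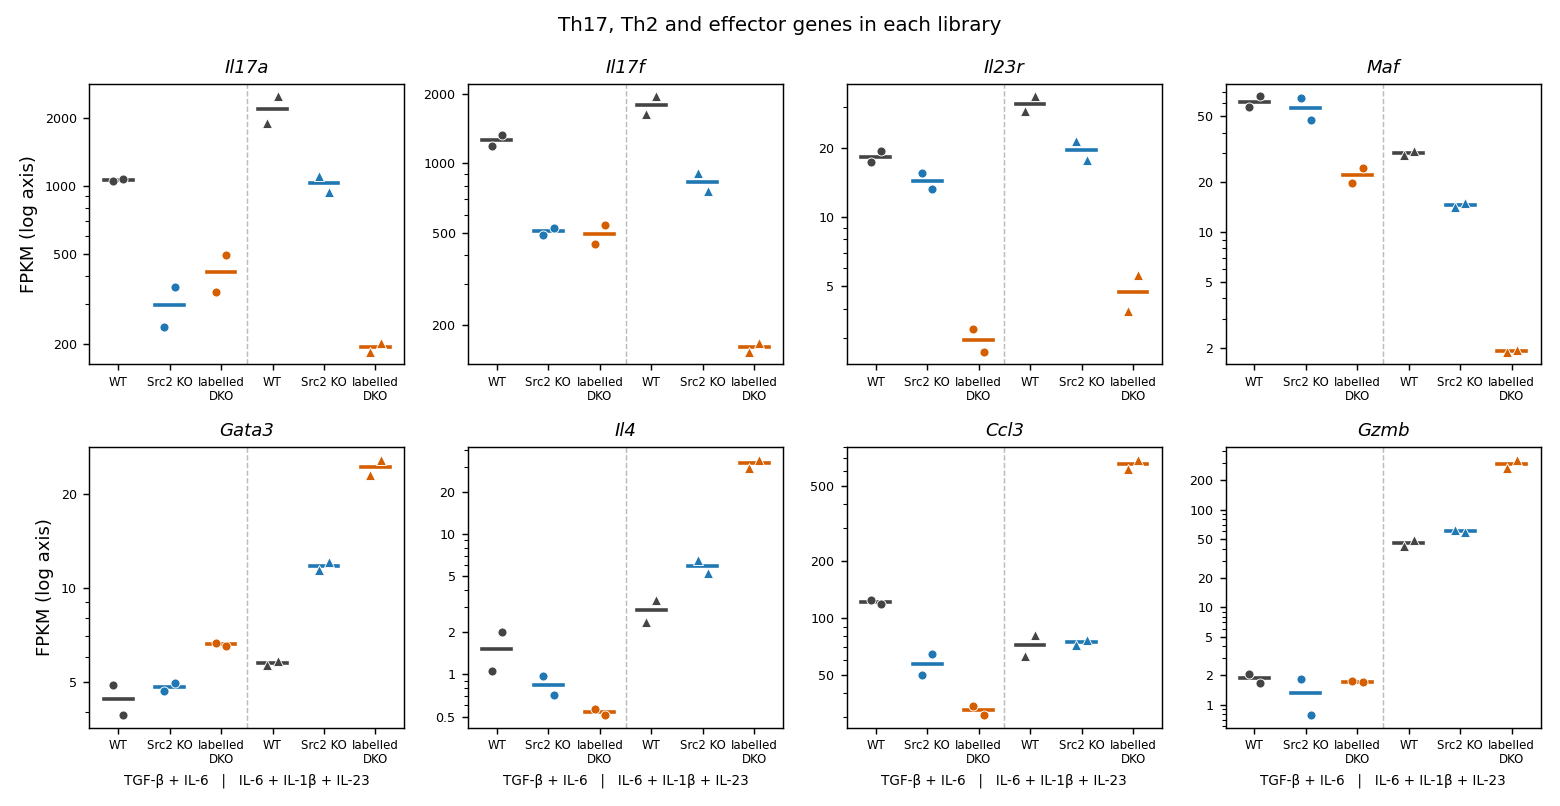
FPKM on log axes of 8 genes in each library; points are libraries and lines group means, with the TGF-β condition left of the dashed line in each panel. In the IL-23 condition the labelled DKO libraries are lowest for Il17a, Il17f and Maf (means 192, 159 and 1.93 FPKM) and highest for Gata3, Il4, Ccl3 and Gzmb (means 24.4, 31.8, 649 and 297 FPKM).

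By list, 12 of 16 core Th17 genes fell and none rose (adjusted p = 1.21e-11; adjusted p = 0.0713 with an estimated correlation). Of 7 Th2 genes 6 rose while Il4ra, the receptor of IL-4, fell by 1.00 on the log2 scale (adjusted p = 1.92e-05; adjusted p = 0.0713 with an estimated correlation). Of 19 interferon-stimulated genes 15 rose (adjusted p = 2.47e-11; adjusted p = 0.103 with an estimated correlation), among them Usp18 (2.31), Irf7 (1.80) and Zbp1 (1.40). Of 25 early T cell receptor response genes 14 rose and 3 fell (adjusted p = 9.12e-05; adjusted p = 0.195 with an estimated correlation); Egr3 rose by 1.64. Cholesterol synthesis genes fell again, 17 of 24 with none risen (adjusted p = 2.47e-11; adjusted p = 0.13 with an estimated correlation), among them Insig1 (-1.11) and Lss (-1.03). The list of pathogenic Th17 genes was higher as a whole (8 of 16 rose and 3 fell, adjusted p = 0.00459; adjusted p = 0.176 with an estimated correlation): those that rose included Ccl3, Ccl4, Csf2, Gzmb and Il3, and those that fell were Il22, Il23r and Tbx21. The naive and memory (7 of 12 fell), homing (9 of 20 fell), fatty acid (5 of 17 fell) and glycolysis lists (4 of 20 fell) were lower. So were the SRC family list (2 of 3 fell, Ncoa1 and the targeted Ncoa3) and the non-pathogenic Th17 list (4 of 7 fell and 1 rose). T cell identity was higher (3 of 14 rose and 1 fell). These 7 lists passed at adjusted p = 0.000251 to 0.0276 (adjusted p = 0.101 to 0.383 with an estimated correlation). Naive and memory, homing and T cell identity lists each had 1 gene against their direction. Markers of CD8 T and natural killer cells went both ways: Cd8b1, a chain of the CD8 receptor, rose from 9.24 ± 0.41 to 19.7 ± 0.57 FPKM (1.06, adjusted p = 0.0058). Nkg7, a granule gene of cytotoxic cells, fell from 19.6 ± 0.98 to 8.11 ± 0.89 FPKM (-1.22, adjusted p = 0.00452). Of 5 genes of the B cell list 2 rose, H2-Eb1 (0.81, adjusted p = 0.0341) and Ighm (0.54, adjusted p = 0.0367), and the list did not pass (adjusted p = 0.0748). Both calls ended without WT replicate 2 or either labelled DKO library of this condition, and without either WT library or labelled DKO replicate 2 of the TGF-β condition. That of H2-Eb1 also ended without WT replicate 1 of this condition, and that of Ighm without labelled DKO replicate 1 of the TGF-β condition. In all 1877 genes passed, 905 higher and 972 lower in labelled DKO cells. The count was 1192 and 899 without WT replicate 1 and 2, 989 without labelled DKO replicate 2 and 1190 in a fit of the 4 libraries alone. The calls of the homing and non-pathogenic Th17 lists ended without WT replicate 1 or labelled DKO replicate 1, and that of Ifng without WT replicate 2 and with a pseudocount of 0.1.

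Labelled DKO cells were also compared with Src2 KO cells, to separate what is added to the Src2 KO effect; since Ncoa2 differed between these lines, the comparison does not isolate SRC3. In the TGF-β condition Il17a (0.49, adjusted p = 0.205) and Il17f (-0.04, adjusted p = 0.881) did not differ past the test, and neither did Csf2, Foxp3, Ifng, Il10 or Il22 (adjusted p = 0.201 or above). Il23r was lower in labelled DKO cells (2.93 ± 0.46 against 14.3 ± 1.6 FPKM, log2 fold change -2.11, adjusted p = 0.000512), as were Tbx21 (-1.08), Adam8, a metalloprotease (-2.34), and Scd1 (-1.91). Nppc (2.25), Tagap (1.74), Gbp2 (1.44), Ccr6 (1.31), Rel, an NF-κB subunit (0.90), and the activation marker Cd69 (0.85) were higher. Of 25 early T cell receptor response genes 11 were higher and 1 lower (adjusted p = 1.18e-06; adjusted p = 0.42 with an estimated correlation). Of 24 cholesterol genes 15 were lower and none higher, Hmgcs1 by 0.97 and Mvd by 0.81 below (adjusted p = 1.98e-14; adjusted p = 0.42 with an estimated correlation). Of 20 glycolysis genes 4 were lower, the lactate transporter Slc16a3 among them (-0.71; list adjusted p = 1.18e-06; adjusted p = 0.582 with an estimated correlation). The cell cycle list was higher (0 of 27 genes past the test, adjusted p = 0.0158; adjusted p = 0.643 with an estimated correlation). It turned lower, at adjusted p = 0.28, without Src2 KO replicate 1, the library with low cell cycle genes; its call also ended without labelled DKO replicate 1. The interferon list was higher (6 of 19 higher and 1 lower, adjusted p = 0.0158; adjusted p = 0.582 with an estimated correlation), a call that ended without labelled DKO replicate 1 and with genes above 1 RPM. The non-pathogenic Th17 list was lower (2 of 7, adjusted p = 0.0483; adjusted p = 0.42 with an estimated correlation), a call that ended under each other scaling tried, without Src2 KO replicate 2, labelled DKO replicate 1 or either Src2 KO library of the IL-23 condition.

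In this comparison 1042 genes passed, 541 higher and 501 lower in labelled DKO cells. The count was 315 and 2745 without Src2 KO replicate 1 and 2, 299 and 175 without labelled DKO replicate 1 and 2, and 677 and 672 without WT replicate 1 and 2 of the TGF-β condition. A fit of the 4 libraries alone called 9 genes; of the genes named here Nppc, Ncoa3 and Ighm kept their call in it. The calls of Ccr6 and Slc16a3 ended without labelled DKO replicate 2. Of markers of other cells Ighm (1.45, adjusted p = 0.00105), Cd74 (0.96, adjusted p = 0.036) and Nkg7 (0.86, adjusted p = 0.0384) were higher and Cst3 was lower (-0.38, adjusted p = 0.0243). The B cell list (adjusted p = 0.537, median -0.08 and mean 0.08) and the CD8 and natural killer list (adjusted p = 0.272) did not pass. The calls of Cd74, Nkg7 and Cst3 ended without Src2 KO replicate 1 or either labelled DKO library. Those of Cd74 and Nkg7 also ended without either WT library of the TGF-β condition or either Src2 KO library of the IL-23 condition, and that of Nkg7 without any other library of the IL-23 condition.

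In the IL-23 condition Il17a was lower in labelled DKO than in Src2 KO cells, at 192 ± 12 against 1024 ± 117 FPKM (log2 fold change -2.40, adjusted p = 0.000362) and so was Il17f, at 159 ± 9.2 against 833 ± 101 FPKM (-2.38, adjusted p = 4.17e-05). Maf (-2.64), Cd24a (-2.51), Il22 (-2.32), Il23r (-1.95) and Tbx21 (-1.28) were lower. Ccl3 was at 649 ± 54 against 74.3 ± 2.7 FPKM (3.12, adjusted p = 2.11e-05), and Fasl (3.04), Nppc (2.91), Il4 (2.34), Areg, amphiregulin (2.03), the inflammatory caspase gene Casp1 (1.77), Ifng (1.41), Csf2 (1.24), Foxp3 (1.19) and Egr2 (0.78) were higher. Il10 did not pass (0.19, adjusted p = 0.858). Of 16 core Th17 genes 10 were lower (adjusted p = 6.41e-10), and of 7 Th2 genes 5 were higher and 1 lower (adjusted p = 0.000586). Of 19 interferon-stimulated genes 14 were higher, Usp18 by 2.14 and Irf7 by 1.55 (adjusted p = 5.19e-12). Each of these 3 lists had an adjusted p = 0.093 with an estimated correlation. Of 25 early T cell receptor response genes 15 were higher and 2 lower (adjusted p = 6.49e-06) and of 24 cholesterol genes 8 were lower, Insig1 (-0.82) and Lss (-0.71) among them (adjusted p = 3.08e-07), both with an adjusted p = 0.197 with an estimated correlation. The pathogenic Th17 (8 of 16 higher, 3 lower) and T cell identity lists (4 of 14 higher) were higher and the glycolysis, fatty acid, homing, naive and memory, and non-pathogenic Th17 lists lower. These 7 passed at adjusted p = 1.15e-05 to 0.0285 (adjusted p = 0.093 to 0.279 with an estimated correlation). In all 1285 genes passed, 663 higher and 622 lower; the count was 675 and 610 without Src2 KO replicate 1 and 2, 519 without labelled DKO replicate 2 and 444 in a fit of the 4 libraries alone. The calls of Csf2 and Il22 ended without Src2 KO replicate 1, that of Csf2 also without labelled DKO replicate 2, and that of the non-pathogenic Th17 list without labelled DKO replicate 1. In the fit of the 4 libraries the calls of Lss, Il22, Ifng and Ighm ended. Of markers of other cells Ighm (0.79, adjusted p = 0.00939) and Cd8b1 (0.74, adjusted p = 0.0408) were higher, and the B cell (adjusted p = 0.18) and CD8 and natural killer lists (adjusted p = 0.795) did not pass. The call of Ighm ended without labelled DKO replicate 2, and that of Cd8b1 without any 1 of the 4 libraries compared, any WT library or either labelled DKO library of the TGF-β condition.

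Whether a genotype effect differed between the cytokine conditions was tested as the difference of the 2 effects, IL-23 condition minus TGF-β condition. For the labelled DKO effect, the difference was positive for Ccl3 (log2 difference 5.06, SE 0.21, adjusted p = 1.72e-05), which fell in the TGF-β condition and rose in the IL-23 condition, and for Il4 (4.20), Ccl4 (3.42), Fasl (3.24), Il3 (3.20), Il13 (2.90), Gzmb (2.77) and Gata3 (1.45). It was negative for Cd24a (-2.57), Ccr6 (-2.26), Maf (-2.21), Il17f (-2.14, SE 0.20, adjusted p = 0.000791) and Il17a (-2.11, SE 0.33, adjusted p = 0.0092). Csf2 (1.81, adjusted p = 0.019) and Foxp3 (1.21, adjusted p = 0.0445) passed as well. Il22 passed too (-3.14, adjusted p = 0.0194), but in the TGF-β condition it was at 0.138 ± 0.20 FPKM in WT and 0.0283 ± 0.040 in labelled DKO cells, under the pseudocount of 0.5, which holds its effect there near 0. Its difference therefore shows the effect in the IL-23 condition and not that the effects differ. Mean Il13 was also under the pseudocount in the TGF-β condition (0.315 ± 0.087 and 0.470 ± 0.30 FPKM), and the same holds for it. Il23r (-0.14), Tbx21 (0.06), Ifng (1.09) and Il10 (1.18) did not pass, at adjusted p = 0.105 or above. The effect on the core Th17 list was more negative in the IL-23 condition (8 of 16 genes fell and 1 rose in this test, adjusted p = 9.47e-05; adjusted p = 0.25 with an estimated correlation). It was more positive on the pathogenic Th17 list (6 of 16 and 1 in the other direction, adjusted p = 2.86e-05; 0.165 with an estimated correlation). The same held for the Th2 list (4 of 7 with Il13 among them, adjusted p = 0.000208, or 0.165 with an estimated correlation). It also held for the interferon list (5 of 19, adjusted p = 9.42e-06, or 0.265 with an estimated correlation). The limit given for Il22 and Il13 also applies where they count in the core Th17, pathogenic Th17 and Th2 lists. The early T cell receptor (7 of 25 genes higher, 2 lower), mitochondrial genome (0 of 15) and T cell identity lists (1 of 14 higher) passed as higher. The cell cycle (0 of 27), homing (4 of 20 lower) and naive and memory lists (3 of 12 lower, 1 higher) passed as lower. These 6 stood at adjusted p = 0.00707 to 0.0467 (adjusted p = 0.202 to 0.673 with an estimated correlation). Each of these 6 lost its call without labelled DKO replicate 1 or WT replicate 1 of the IL-23 condition, at adjusted p = 0.055 to 0.282. For cholesterol genes the effects did not differ past the test (0 of 24 genes, list adjusted p = 0.153). In all, 508 genes passed, 275 with a higher and 233 with a lower effect in the IL-23 condition. The count was 180 and 183 without WT replicate 1 and 2 of the TGF-β condition, and 256 and 219 without those of the IL-23 condition. It was 197 and 167 without labelled DKO replicate 1 and 2 of the TGF-β condition, and 213 without replicate 2 of the IL-23 condition. It was 780 and 777 without Src2 KO replicate 1 and 2 of the TGF-β condition, and 857 in a fit without the Src2 KO libraries. The calls of Csf2 and Foxp3 ended without any WT or labelled DKO library of the TGF-β condition and without WT replicate 1 or labelled DKO replicate 2 of the IL-23 condition, and that of Foxp3 also without labelled DKO replicate 1 there. That of Il22 ended without WT replicate 1 or either labelled DKO library of the TGF-β condition and without WT replicate 2 of the IL-23 condition. Voom on recovered reads ended the calls of Il13 and Il22.

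**Figure D4:**
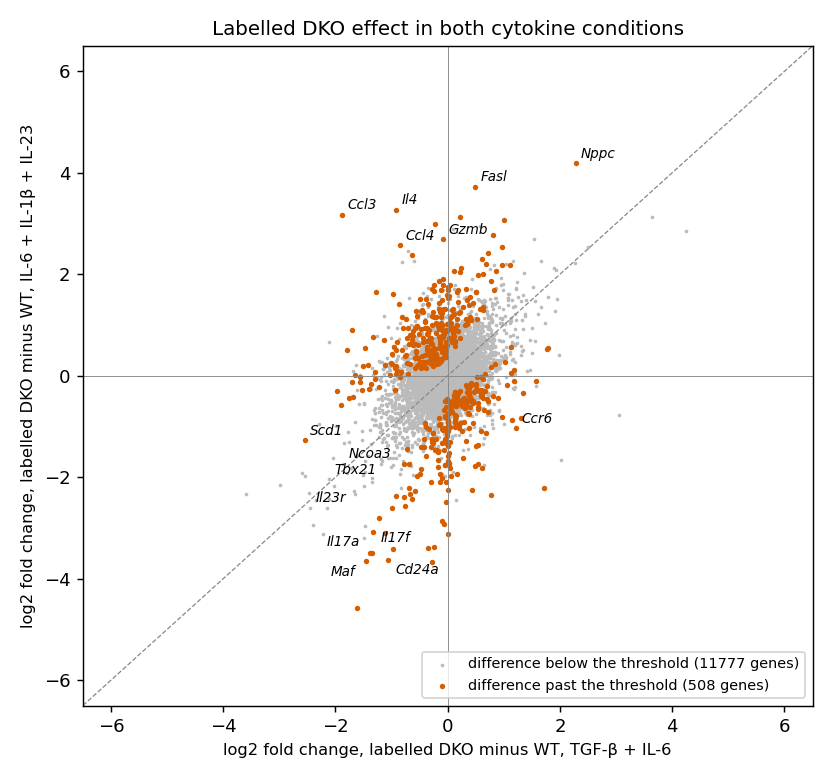
Log2 fold change of labelled DKO against WT for 12285 genes, with the TGF-β condition on the x axis and the IL-23 condition on the y axis; the dashed line marks equal effects. The 508 genes in orange passed the test of the difference, among them Ccl3 (-1.89 and 3.17) and Il17f (-1.35 and -3.48).

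For the Src2 KO effect no gene passed the test of the difference between conditions in limma (532 at an unadjusted p under 0.05, smallest adjusted p = 0.351), and voom on recovered reads called 0 as well. With libraries left out in turn, 1 gene passed without Src2 KO replicate 2 of the IL-23 condition. The difference was 0.78 for Il17a and 0.20 for Il17f, both at an adjusted p of 1. The difference passed for the Th2 list (higher in the IL-23 condition, adjusted p = 4.4e-06; adjusted p = 0.0941 with an estimated correlation) and the early T cell receptor list (higher, adjusted p = 2.86e-06; adjusted p = 0.412 with an estimated correlation). In these lists 3 of 7 and 1 of 25 genes passed adjusted over the list alone. The 3 Th2 genes were Gata3, Il4 and Il13. In the TGF-β condition Il13 was at 0.315 ± 0.087 FPKM in WT and 0.349 ± 0.052 in Src2 KO cells, under the pseudocount. Its difference therefore shows the IL-23 condition and not that the effects differ. The pathogenic Th17, follicular helper and homing lists (higher) and the cholesterol and glycolysis lists (lower) passed at adjusted p = 0.00799 to 0.0422 (adjusted p = 0.412 to 0.636 with an estimated correlation). The call of each of these 5 ended without Src2 KO replicate 2 or WT replicate 2 of the IL-23 condition and without 1 or more libraries of the TGF-β condition.

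Fold changes were compared across the 12285 genes, which are not independent replicates, so no p is given. The labelled DKO effects of both conditions, which share no library, had Pearson r = 0.381 (0.001 in simulated unchanged groups). In both, 411 genes passed: 183 higher in both, 194 lower in both and 34 in opposite directions, where independent calls would give 25.7, 30.9 and 56.4. Both tests use the same variance of each gene, which raises overlaps in any direction, so these numbers may be too low as a chance level. The Src2 KO effects of both conditions had r = 0.28 (-0.003 in simulated groups). The Src2 KO and labelled DKO effects, which share their WT libraries, had r = 0.222 in the TGF-β condition and 0.511 in the IL-23 condition, where simulated unchanged groups that share WT gave 0.499 and 0.503. Their covariance differed from the simulated one by -0.00141 and 0.0401, differences that were not tested. In the TGF-β condition 7 genes were lower in both comparisons and 1 higher in both, where independent comparisons would give 0.35 and 0.0568. In the IL-23 condition 17 were lower in both and 7 higher in both, where independent comparisons would give 1.66 and 0.663. The comparisons share their WT libraries, which raises such overlaps, so these counts are not evidence of a shared effect. In the TGF-β condition r was -0.033 without Src2 KO replicate 2 and 0.432 without Src2 KO replicate 1. The apoptosis and B cell lists passed in none of the 9 comparisons, and the γδ T cell, myeloid and erythroid lists had fewer than 3 genes to test.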

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

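All tests of explanations in this part were chosen only after the result was seen; the tests of the difference between conditions were planned.

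The labelled DKO effect differed between the cytokine conditions for 508 genes and 10 gene lists. The log2 difference, IL-23 minus TGF-β condition, was 5.06 for Ccl3, 4.20 for Il4, 3.42 for Ccl4, 3.24 for Fasl, 3.20 for Il3, 2.90 for Il13, 2.77 for Gzmb, 1.81 for Csf2, 1.45 for Gata3 and 1.21 for Foxp3. It was -3.14 for Il22, -2.57 for Cd24a, -2.26 for Ccr6, -2.21 for Maf, -2.14 for Il17f and -2.11 for Il17a. Mean Il22 and Il13 were under the pseudocount in the TGF-β condition in WT and labelled DKO cells, which holds their effects there near 0, so their differences show the IL-23 condition and not that the effects differ. The adjusted p was 9.47e-05 for the core Th17 list, 2.86e-05 for pathogenic Th17, 0.000208 for Th2, and 9.42e-06 for interferon. It was 0.022 for the early T cell receptor response, 0.019 for the cell cycle, 0.0467 for homing, 0.0176 for naive and memory, 0.0404 for the mitochondrial genome and 0.00707 for T cell identity. None of these lists passed with an estimated correlation.

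A scaling factor per library moves all genes one way, so it cannot give both the 157 higher and the 120 lower genes with at least a 2-fold difference. The libraries were already scaled to a median difference near 0 (-0.006), so this split does not test a shift shared by most genes. A single library would carry the difference away with it, but at least 163 of the 508 genes still differed in the same direction without any 1 library. More CD8 T and natural killer cells together would raise the markers of both, but Nkg7 fell (-1.22) where Cd8b1 rose (1.06). Gene totals do not show which cells of a culture a transcript came from, so a fall of Nkg7 in the CD4 T cells could hide such cells. A change in 1 or both of these cell types therefore stays open. B cell markers, of which 2 of 5 rose, were not weighed. Also open is the hypothesis that the response to the labelled DKO genotype depends on the cytokines, found and tested on the same libraries.

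The Src2 KO effect differed between conditions for 7 lists and for 0 genes in limma (532 at an unadjusted p under 0.05; voom called 0). The adjusted p was 4.4e-06 for Th2, 2.86e-06 for the early T cell receptor response, 0.00799 for cholesterol, 0.0102 for follicular helper cells, 0.0157 for glycolysis, 0.0351 for homing and 0.0422 for pathogenic Th17 genes. With an estimated correlation 0 of these lists passed, at adjusted p = 0.0941 to 0.636. The glycolysis difference was at an adjusted p of 0.99 without Src2 KO replicate 1 of the TGF-β condition.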

How the results depend on the processing

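The alternatives with TMM, total reads and other pseudocounts were chosen after seeing the data, and the others before; where no cause is given, the cause was not tested. Planned fits with DESeq2 and edgeR were written for deposited counts and were not run on these FPKM values. The recovered reads would have allowed them, and voom was the fit run on those reads. Counts of genes follow in the order Src2 KO minus WT, labelled DKO minus WT and labelled DKO minus Src2 KO in the TGF-β condition, the same 3 in the IL-23 condition, IL-23 minus TGF-β condition in WT, and the Src2 KO and labelled DKO effects compared between conditions. As reported they were 13, 740, 1042, 30, 1877, 1285, 3540, 0 and 508. A threshold of 0.01 for the adjusted p, stricter by construction, gave 2, 240, 278, 10, 917, 533, 1899, 0 and 155, and treat against a fold of 1.5, stricter too, gave 2, 46, 45, 3, 277, 112, 527, 0 and 52. A fit of the libraries of the comparison alone gave 1, 1514, 9, 2, 1190, 444, 4124, 0 and 857. That fit has fewer samples and takes the variance from the compared groups only. Fewer samples alone cannot account for the counts that rose, and the cause was not tested. The labels do not say whether replicate numbers pair libraries across groups. Replicate deviations correlated between groups at -0.318 to 0.217 over 15 pairs of groups, which cannot show whether animals or batches were shared. A block on the replicate numbers within each condition gave 2, 374, 514, 13, 1395, 830, 1832, 0 and 235. Over all libraries such a block gave 6 for the first. Voom on recovered reads gave 51 and 61 for Src2 KO minus WT in the TGF-β and IL-23 conditions, genes above 1 RPM gave 54 and 49, and no filter gave 21 in the TGF-β condition. The other scalings and pseudocounts kept each count within 1.5 times the reported one and moved the median of all genes by at most 0.04 on the log2 scale.

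Leaving out each library in turn gave 1 to 75, 152 to 1179, 175 to 2745, 4 to 37, 899 to 2268, 519 to 1582, 1993 to 4129, 0 to 1 and 167 to 780 genes. Lists called, in the same order, were 9, 12, 6, 7, 13, 12, 11, 7 and 10 as reported and 0 in each with an estimated correlation. With libraries left out they were 4 to 12, 11 to 13, 5 to 7, 4 to 10, 11 to 15, 11 to 13, 8 to 14, 3 to 8 and 5 to 12. Fry, which does not compare a list with other genes, called 4, 13, 7, 5, 16, 16, 14, 1 and 9. The cell cycle list turned from higher to lower in labelled DKO minus Src2 KO of the TGF-β condition without Src2 KO replicate 1, at an adjusted p of 0.28. Fold-change correlations without single libraries were -0.033 to 0.432 for Src2 KO with labelled DKO in the TGF-β condition and 0.412 to 0.609 in the IL-23 condition, 0.153 to 0.28 for Src2 KO across conditions and 0.31 to 0.395 for labelled DKO across conditions. With genes above 1 RPM the last pair were 0.342 and 0.409. Of 495 calls of named genes none reversed. Voom ended 8, the replicate block 28 over all libraries and 85 within each condition, the libraries of the comparison alone 133, and single libraries left out 1 to 100. Depth of 14880920 to 16586604 reads limits genes of low value, and 2 libraries per group limit small changes.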

Other observations

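All tests in this part were chosen only after the result was seen.

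Ncoa2 was near the WT level in libraries labelled DKO. The lower 95% bound of the log2 difference, labelled DKO minus Src2 KO, was 0.53 in the condition where it was lower. That bound restates that Ncoa2 was not equally low in both knockout lines, and it tests no cause of it. The tables argue against a swap of WT with labelled DKO libraries, as the highest labelled DKO library had 31.4% of the Ncoa3 of the lowest WT library of its condition. An Src2 allele in the labelled DKO line that leaves most Ncoa2 reads in place cannot be told apart from an intact Src2 gene: Ncoa2 was at 84.7% of WT in the lower condition, and gene totals hold no exon values. A difference that is due to loss of SRC3 with SRC2 intact stays open for every labelled DKO comparison.

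Src2 KO replicate 1 of the TGF-β condition stood apart from replicate 2, with a chi-square per gene of 27.2 between them against 4.47 to 16.3 in the other 5 pairs. Cells of the IL-23 cultures in that library would bring their abundant transcripts. Each of the 15 genes near absent in the TGF-β condition allows a share of such cells, with a median of 0.594% and a highest value of 4.08%. The position of the library on the first component would need 18.0%, taken as a straight distance. That component was computed from log2 values, on which mixing is not linear, so these shares cannot be compared. Whether such cells moved the library was therefore not decided. Fewer dividing cells may be part of the difference: the cell cycle list had a median log2 difference of -1.19 with all 27 genes lower, and Rrm2 was at 7.75 against 31.5 FPKM. The B cell list was higher by a median of 0.39 (quartiles -0.03 and 1.06, 2 of 5 genes lower), the stress list by 0.38, the glycolysis list by 0.34 and the mitochondrial genome list by 0.23 (2 of 15 genes lower). What lowered the cell cycle genes was not tested, as both libraries carry the same labels.

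In the IL-23 condition, higher cytokine and chemokine genes in labelled DKO cells may come from a stronger response to anti-CD3. Other cytokine genes fell in these cells against WT: Il17a (log2 fold change -3.49), Il17f (-3.48) and Il22 (-3.38). The early T cell receptor list holds Cd40lg, itself among the genes that rose in this condition (2.04), so it is not separate from the genes to be explained. The early T cell receptor list was higher there (median log2 fold change 0.62), but its difference between conditions reached an adjusted p of 0.103 when 1 library was left out, so this stays undecided.

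Some genes set a line apart in all of its libraries. Gm33707, a processed pseudogene on chromosome 3, was at 0.33 to 0.84 FPKM in WT, 22.3 to 29.6 in Src2 KO and 7.82 to 16.9 in labelled DKO libraries. Capn11 was at 0 to 0.02 FPKM in Src2 KO, 0.93 to 1.07 in WT and 0.99 to 1.42 in labelled DKO libraries. Nrp1 was at 10.9 to 14.3 FPKM in labelled DKO libraries and at most 4.52 in the others. The cause of these differences between lines was not tested.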
